A study of Homo sapiens with 5 samples.

How the data were processed

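The study measured polyadenylated RNA, labelled with biotin per the labels, on Affymetrix oligonucleotide arrays. There were 5 arrays, each the 1 array of its group. Per the labels, the control bead array carried mRNA bound to an unmodified bead. The Tblink bead, Tbr bead, tobramycin interference and neomycin interference arrays carried commercial human liver mRNA. The names Tblink and Tbr are used as the labels give them, since they are not spelled out there. Aminoglycoside doses, incubation times and amounts of beads or RNA are not given in the sources used here.

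The deposited values are an intensity per probe set and array on a linear scale. Per the submitters' processing notes they were made with GCOS, the Affymetrix operating software. Its version, signal settings and scaling target are not given in the sources used here. The 2% trimmed mean of the deposited values was 250.0 on the control bead array and the same to 3 digits on the others, so the values had been scaled array by array before deposit. Such scaling gives an array with little target the same trimmed mean as an array with much, and raises its background. No probe-level values were used here.

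Of 54675 probe sets, 62 are Affymetrix control probe sets and were kept out of the comparisons, which left 54613. The platform annotation listed 1 gene symbol for 41091 of them, several for 1801 and none for 11721, which are unnamed here. The probe sets with 1 symbol stand for 19775 genes. The probe set with the highest mean log2 signal over the 5 arrays represented its gene. Probe sets ending in _x_at or _s_at can take RNA of several genes. No genome was used here, so no coordinates are given.

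In the main setting each array was multiplied so that its 2% trimmed mean was 500, values under a floor of 100 were set to 100, and log2 was taken. A probe set entered a comparison where the brighter of the 2 arrays had at least 400, and was counted at a difference of at least 4-fold. Where the dimmer value of a named gene was under the median of its array, or under the floor at equal hybridization controls, it was taken as background. The fold is then a lower bound, written "at least", of the brighter value over the higher of the dimmer value and that median, a rule chosen after the data had been seen. List medians and counts keep the floored values. At equal controls a fold against the floor is a lower bound too. Beside this stands a scaling to equal hybridization controls. For it each array was divided by its geometric mean signal over 9 probe sets for BioB, BioC, BioD and Cre, transcripts that the array maker supplies for addition to the hybridization mix, and the neomycin interference array, with the lowest control signal, kept a trimmed mean of 500. That scaling assumes equal added controls on all arrays, which the labels do not state.

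With 1 array per group no test between groups was made, no p-value is given, and no difference has a replicate check; the number of arrays limits the precision. The only repeated measurement within an array is that by different probe sets of a gene. From pairs of such probe sets a robust SD of the log2 ratio of a single probe set was computed for each comparison, called the probe set spread. It does not cover the spread between samples.

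The 6 comparisons, the thresholds, the rule for named genes and 25 gene lists were fixed before the data were examined. The lists have 384 memberships, 329 of them with a named probe set. The median log2 ratio of a list's members that passed the brightness minimum was set beside the central 95% of medians of 10000 random lists of the same size, matched on the decile of mean log2 signal of the 2 arrays. This range is a description of these arrays. The highest decile has no upper limit, so members far brighter than the rest of it are not matched on signal. Where the other array is near background, a list of very bright members may pass its range for this reason alone, which was not tested. Lists with under 3 measured members have no value. Named genes are, per comparison, the 10 highest and the 10 lowest log2 ratios among genes whose bright probe sets all had the same sign, and the 4 members of each list with the highest mean log2 signal. XIST and Y-linked genes were left out. The text gives part of these genes, and says where a gene was chosen after its values were seen.

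Alternatives were floors of 50 and 200, values as deposited, quantile normalization, the hybridization control scaling, a brightness minimum of 1000, leaving out _x_at and _s_at probe sets, and the mean of all bright probe sets of a gene. A brightness minimum of 3000, 2 comparisons of bead arrays with the tobramycin array, and, for lists and genes, the hybridization control scaling and the values as deposited were added after the data had been seen. The counting rule was tested on simulated data for the tobramycin against neomycin comparison over 54613 probe sets, with noise of the size of its probe set spread. It recovered 100.0% of 100 probe sets changed 8-fold and 52.0% of 100 changed by 4-fold, the threshold itself, and called 0 unchanged probe sets. With that spread at 0.24 on the log2 scale, these outcomes largely follow from the settings. The other planned comparisons had spreads of 2.07 to 2.44, wider than the 4-fold threshold. They were not simulated, so the simulation says nothing about calls there. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.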

Results

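Human mRNA, from liver where the labels give its source, was profiled on 5 arrays to ask how aminoglycosides, antibiotics that bind RNA, affect the mRNAs measured on a DNA array. The groups were an unmodified control bead, the Tblink bead, the Tbr bead, and liver mRNA in what the labels call tobramycin or neomycin interference. Each group had 1 array, so the values below have no replicate error. No array held liver mRNA without a bead or an aminoglycoside, so the effect of either aminoglycoside by itself cannot be read.

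The arrays differed in how much mRNA signal they held against the hybridization controls. Transferrin mRNA (TF), for the iron carrier of plasma, had signals at equal hybridization controls of 99.7 on the control bead, 1695 on the Tblink bead, 17063 on the Tbr bead, 34755 with tobramycin and 35538 with neomycin. On the same arrays in that order APOC3, an apolipoprotein of triglyceride-rich particles, had 1.39, 40.6, 12253, 46408 and 43159.7, and LDHA, a lactate dehydrogenase subunit, had 1.05, 27.7, 708, 33771 and 33552. With each trimmed mean at 500 the order was another: TF had 12505 on the control bead, 253480.1 on the Tblink bead, 452054 on the Tbr bead, 35669.8 with tobramycin and 35538 with neomycin.

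At that common trimmed mean the hybridization controls averaged 4005 on the neomycin array. They were 1.03-fold this level on the tobramycin array, 26.5-fold on the Tbr bead array, 125-fold on the control bead array and 149.6-fold on the Tblink bead array. A further control set, 12 poly-A control probe sets, had 2.07 times the hybridization control signal on the control bead. It had 1.58 times on the Tblink bead, 1.60 on the Tbr bead, 0.66 with tobramycin and 0.67 with neomycin. Folds between bead and interference arrays at equal controls thus depend on the control set used. At equal controls a signal of 400 was reached by 1 probe set on the control bead array, 19 on the Tblink bead array, 531 on the Tbr bead array, 15366 on the tobramycin array and 15552 on the neomycin array. The 1 on the control bead array, named after its value was seen, was NNMT, a methyltransferase of nicotinamide, at 1089.9. The median log2 ratio of all bright genes moved with the scaling, for the Tbr bead against the control bead from 0.22 at the common trimmed mean to 3.03 at equal controls. The folds and list medians below are at the common trimmed mean unless said otherwise.

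**Figure D1:**
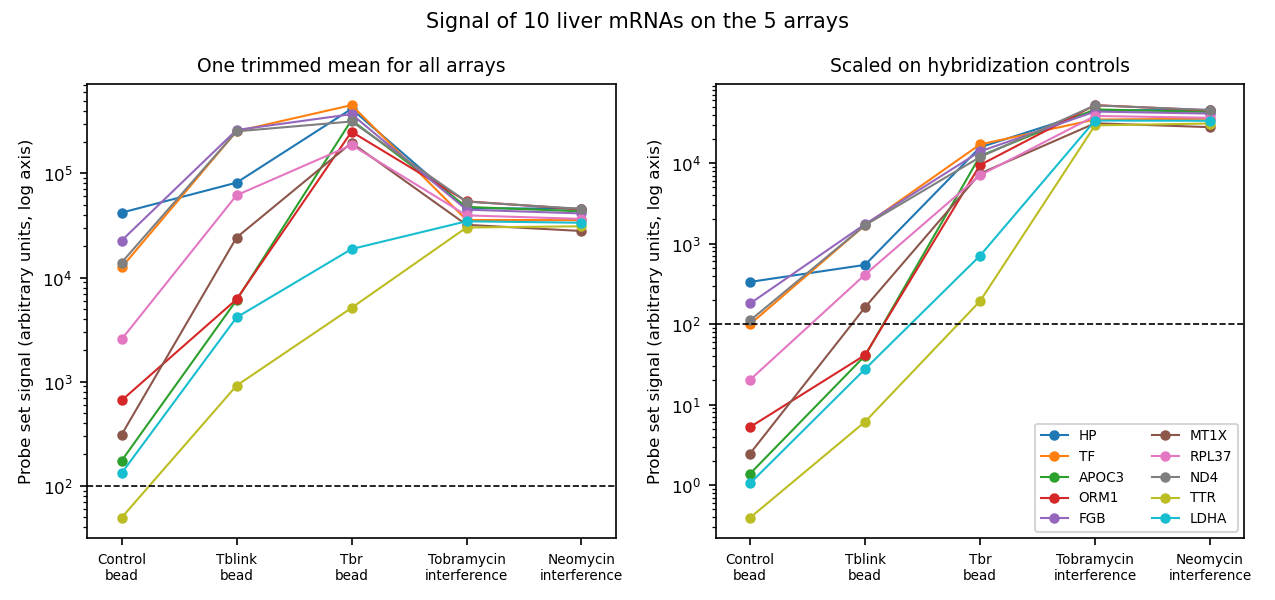
Signal of 10 liver mRNAs (log axis, arbitrary units) on the 5 arrays, 1 per group, at a common trimmed mean of 500 (left) and at equal hybridization controls (right), with the floor of 100 dashed. On the right each gene is lower on the bead arrays than on the interference arrays, while on the left TF, HP and FGB are highest on the Tbr bead array.

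The Tblink bead was set against the unmodified bead to ask which mRNAs it held beyond the control. MT1X, a metallothionein that binds zinc and copper, was at least 78.2-fold higher, RPL10A at least 38.2-fold, RPS29 at least 36.5-fold and APOC3 at least 23.3-fold. GBE1, the glycogen branching enzyme, was at least 34.2-fold higher. TF was at least 20.3-fold higher, FGB, the fibrinogen beta chain, 11.5-fold, and the mitochondrially encoded ND4 and COX1, of the respiratory complexes, 18.2-fold and at least 25.4-fold. At equal hybridization controls MT1X was at least 1.62-fold, TF at least 16.9-fold, FGB 9.67-fold and ND4 15.3-fold higher, while GBE1 and APOC3 were under the floor on both arrays.

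By list, with members counted at 4-fold and the range of random lists beside each median log2 ratio, secreted plasma protein genes stood above their range (12 of 18 higher and 0 lower, median 3.18, range -0.28 to 0.997). So did metallothioneins, whose similar members can share target (6 of 7 higher and 0 lower, median 3.35, range -0.55 to 1.45), nuclear oxidative phosphorylation genes (9 of 17 higher and 0 lower, median 2.86, range -0.60 to 1.32), mitochondrially encoded genes (6 of 7 higher and 0 lower, median 2.54, range -0.55 to 1.45) and housekeeping genes (7 of 13 higher and 0 lower, median 2.56, range -0.72 to 1.16). Cytosolic ribosomal proteins (7 of 14 higher and 0 lower, median 2.15, range -0.45 to 1.14), complement (6 of 15 higher and 0 lower, median 1.66, range -0.62 to 1.13), chaperones (5 of 13 higher and 0 lower, median 1.63, range -0.71 to 1.25) and coagulation genes (7 of 17 higher and 1 lower, median 1.35, range -0.39 to 1.10) were above theirs too. Cholangiocyte markers, of bile duct epithelium, were below their range (1 of 8 higher and 5 lower, median -2.63, range -2.48 to 2.67), with SOX9 at 97.4 on the Tblink and 1077 on the control bead, though this gene was under the floor on both arrays at equal controls. Iron-responsive element mRNAs (4 of 8 higher and 0 lower, median 1.33) and selenoprotein mRNAs (5 of 15 higher and 3 lower, median 1.01) were within their ranges. HP, haptoglobin, was 1.94-fold higher, and RPS6 1.06-fold higher but 1.13-fold lower at equal controls.

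Over all probe sets 10471 were at least 4-fold higher and 9748 lower on the Tblink bead, 51.8% of the calls being higher. The probe set spread was 2.44 on the log2 scale, wider than the 4-fold threshold, and 1.41 from 34 genes where either array had at least 3000. With that brightness minimum 320 were higher and 28 lower, and at equal hybridization controls 16 and 0. These splits largely follow from the minimum. It was reached by 602 probe sets on the Tblink and 178 on the control bead array, and that of 400 at equal controls by 19 and 1. At equal controls only secreted plasma proteins had enough measured members (4), and their median (2.38, range 1.91 to 2.38) was within its range, which the floor on the control bead nearly fixes.

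The Tbr bead was set against the same unmodified bead, so the 2 comparisons share the control array. On the Tbr bead array the 3′ control probe set of GAPDH had 188 times the signal of the 5′ one, against 1.18 times with tobramycin. The 5′ signal on the Tbr bead was under the floor at equal controls, so the ratio of 188 is not exact. How far the low 5′ signal shapes the changes below was not tested. APOC3 was at least 1248-fold higher, MT1X at least 635-fold, ORM1, an acute-phase plasma glycoprotein, at least 379.8-fold, ELOB at least 276-fold and ATP5PF, an ATP synthase subunit, at least 112-fold. OAZ1, the antizyme that limits polyamine synthesis, was at least 422-fold higher, RARRES2, the secreted chemerin, at least 229-fold, FGG, the fibrinogen gamma chain, at least 113-fold and RPS15A at least 87.5-fold. At equal hybridization controls these genes were higher too, APOC3 at least 123-fold, ORM1 at least 94.7-fold, OAZ1 at least 41.5-fold and RPS15A at least 8.59-fold.

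Secreted plasma protein genes stood above their range (17 of 18 higher and 0 lower, median 5.83, range 0.55 to 2.69), with SERPINA3, a plasma protease inhibitor, at least 90.8-fold, APOC1 at least 65.7-fold, TF at least 36.1-fold and HP 9.93-fold higher. Metallothioneins (7 of 7 higher and 0 lower, median 5.83, range 0.17 to 3.70) included MT2A, at least 134-fold higher. Cytosolic ribosomal proteins (15 of 16 higher and 0 lower, median 5.42, range 0.095 to 2.31) included RPS29, at least 143-fold, RPL37, at least 73.4-fold, and RPS6, 2.34-fold higher. Complement genes (12 of 17 higher and 0 lower, median 4.46, range -0.26 to 2.21) included C3, at least 55.8-fold higher, and coagulation genes (12 of 18 higher and 0 lower, median 3.55, range 0.16 to 2.27) the clotting factor gene F9, at least 70.2-fold higher. On the Tbr bead array TF had 452054 and MT2A 273527, far above the 99th percentile of its probe sets, 10336. Matching by decile does not reach such signals, so brightness may account for part of these list positions, which was not tested.

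Nuclear oxidative phosphorylation genes (14 of 17 higher and 0 lower, median 3.95, range -0.077 to 2.28), mitochondrially encoded genes (7 of 7 higher and 0 lower, median 3.89, range 0.17 to 3.70), selenoprotein mRNAs (11 of 15 higher and 0 lower, median 3.26, range -0.096 to 2.53), housekeeping genes (11 of 13 higher and 0 lower, median 3.61, range 0.14 to 2.85) and translation factors (9 of 14 higher and 1 lower, median 3.05, range -0.41 to 2.41) were above their ranges as well. Proteasome genes (12 of 17 higher and 0 lower, median 2.87, range -0.22 to 2.39), chaperones (8 of 13 higher and 0 lower, median 2.71, range -0.20 to 2.60), splicing and RNA-binding protein genes (6 of 14 higher and 1 lower, median 1.92, range -0.86 to 1.66) and glucose and lipid metabolism genes (7 of 13 higher and 1 lower, median 2.14, range -0.91 to 2.12) were also above theirs. SRSF3, of the splicing list, was at least 8.80-fold higher by its brightest probe set, and its log2 ratio was -0.36 as the mean of its probe sets.

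Iron-responsive element mRNAs lay within their range (4 of 8 higher and 1 lower, median 1.88, range -1.30 to 2.62), with FTL, ferritin light chain, at least 58.3-fold higher and EPAS1 at 1937 on the Tbr and 869 on the control bead. So did mRNAs with a reported internal ribosome entry site (5 of 14 higher and 2 lower, median 0.99, range -0.88 to 1.995), cytochrome P450 and conjugating enzymes (6 of 15 higher and 2 lower, median 1.72, range -0.67 to 2.01), amino acid and urea metabolism genes (7 of 15 higher and 2 lower, median 1.64, range -0.46 to 1.99) and histones (2 of 5 higher and 0 lower, median 1.55, range -1.93 to 3.45). CYP2E1, a cytochrome P450, was at least 74.96-fold higher, while TDO2, which degrades tryptophan, had 1009 on the Tbr bead and 1036 on the control bead. Among markers of other cell types, those of Kupffer cells (median 1.38), endothelium (2.56), stellate cells (0.31), lymphocytes (-0.025) and erythroid cells (-0.31) were within their ranges. Cholangiocyte markers were below (0 of 7 higher and 5 lower, median -2.57, range -2.37 to 2.61), and their named members SPP1, AQP1, SOX9 and EPCAM were under the floor on both arrays at equal controls.

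In all 9761 probe sets were at least 4-fold higher and 10180 lower on the Tbr bead (48.9% higher), at a probe set spread of 2.39 on the log2 scale, and 1.73 at 3000 or more. With the minimum of 3000 the counts were 1561 and 34, and at equal controls 531 and 0. Both splits largely follow from the minimum. It was reached by 1926 probe sets on the Tbr and 178 on the control bead array, and that of 400 at equal controls by 531 and 1. At equal controls every measured list was within its range, secreted plasma proteins (6.27, range 5.37 to 6.28), metallothioneins (5.32, range 4.90 to 5.81) and ribosomal proteins (4.99, range 4.87 to 5.66) included. With the control bead at the floor, matching on signal there nearly fixes the ratio. The 10 lowest genes, ZNF746 among them, had 2359 to 2781 on the control bead array and 18.8 to 22.2, under the floor, at equal controls.

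The Tbr and Tblink beads were then set against each other. RARRES2 was at least 201-fold higher on the Tbr bead, A1BG, a plasma glycoprotein, at least 164-fold, ITIH4, an acute-phase plasma protein, at least 105-fold and NDUFA13, of respiratory complex I, at least 81.1-fold. KRT18, a keratin of simple epithelia, was at least 35.1-fold higher, ROMO1 at least 60.4-fold and RPL35 at least 63.2-fold. Some mRNAs bright on both beads differed little, ND4 being 1.24-fold, FGB 1.42-fold, TF 1.78-fold and COX1 1.88-fold higher on the Tbr bead. At equal hybridization controls these were 7.02-fold, 8.01-fold, 10.1-fold and 10.6-fold higher.

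Lists above their ranges were cytosolic ribosomal proteins (11 of 16 higher and 0 lower, median 2.75, range 0.43 to 1.90), secreted plasma proteins (16 of 18 higher and 0 lower, median 2.64, range 0.63 to 1.96), metallothioneins (7 of 7 higher and 0 lower, median 2.56, range 0.22 to 2.38) and amino acid and urea metabolism (8 of 15 higher and 0 lower, median 2.52, range -0.30 to 1.64), in which ASS1, of the urea cycle, was at least 16.3-fold higher. Kupffer cell markers (7 of 13 higher and 0 lower, median 2.30, range -0.93 to 1.26) included CD14 and C1QB, at least 8.29-fold and at least 8.75-fold higher. Coagulation (10 of 18 higher and 0 lower, median 2.27, range 0.30 to 1.79), proteasome (10 of 17 higher and 0 lower, median 2.12, range -0.19 to 1.51), selenoprotein (8 of 16 higher and 1 lower, median 1.96, range -0.13 to 1.55), complement (8 of 17 higher and 0 lower, median 1.82, range 0.037 to 1.60), translation factor (5 of 13 higher and 0 lower, median 1.78, range -0.13 to 1.59) and housekeeping genes (6 of 14 higher and 1 lower, median 1.97, range 0.29 to 1.96) were above theirs too. Mitochondrially encoded genes (0 of 7 higher and 0 lower, median 0.98, range 0.22 to 2.38), iron-responsive element mRNAs (2 of 8 higher and 1 lower, median 0.52, range -0.67 to 1.72) and stellate cell markers (0 of 10 higher and 0 lower, median -0.38, range -0.81 to 1.31) lay within their ranges, and no measured list lay below.

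Over all probe sets 7824 were at least 4-fold higher and 8687 lower on the Tbr bead (47.4% higher), at a probe set spread of 2.13, and 1.25 at 3000 or more. With the minimum of 3000 the counts were 930 and 20, and at equal controls 527 and 0. These too largely follow from the minimum, reached by 1926 probe sets on the Tbr and 602 on the Tblink bead array, with 531 and 19 at 400 or more at equal controls. There every measured list was within its range (secreted plasma proteins 5.00, range 3.65 to 5.06), which the floor on the Tblink bead nearly fixes. Spearman's rho across probe sets, which are not independent replicates, was 0.29 between the Tblink and Tbr bead arrays, 0.12 between the control and Tbr bead arrays and 0.51 between the tobramycin and Tbr bead arrays. Over the 2926 probe sets with at least 3000 on the neomycin array the order was another, at 0.63, 0.27 and 0.45. Choosing them on an array so like the tobramycin array narrows the range of tobramycin signals, which may account for part of the changed order.

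**Figure D2:**
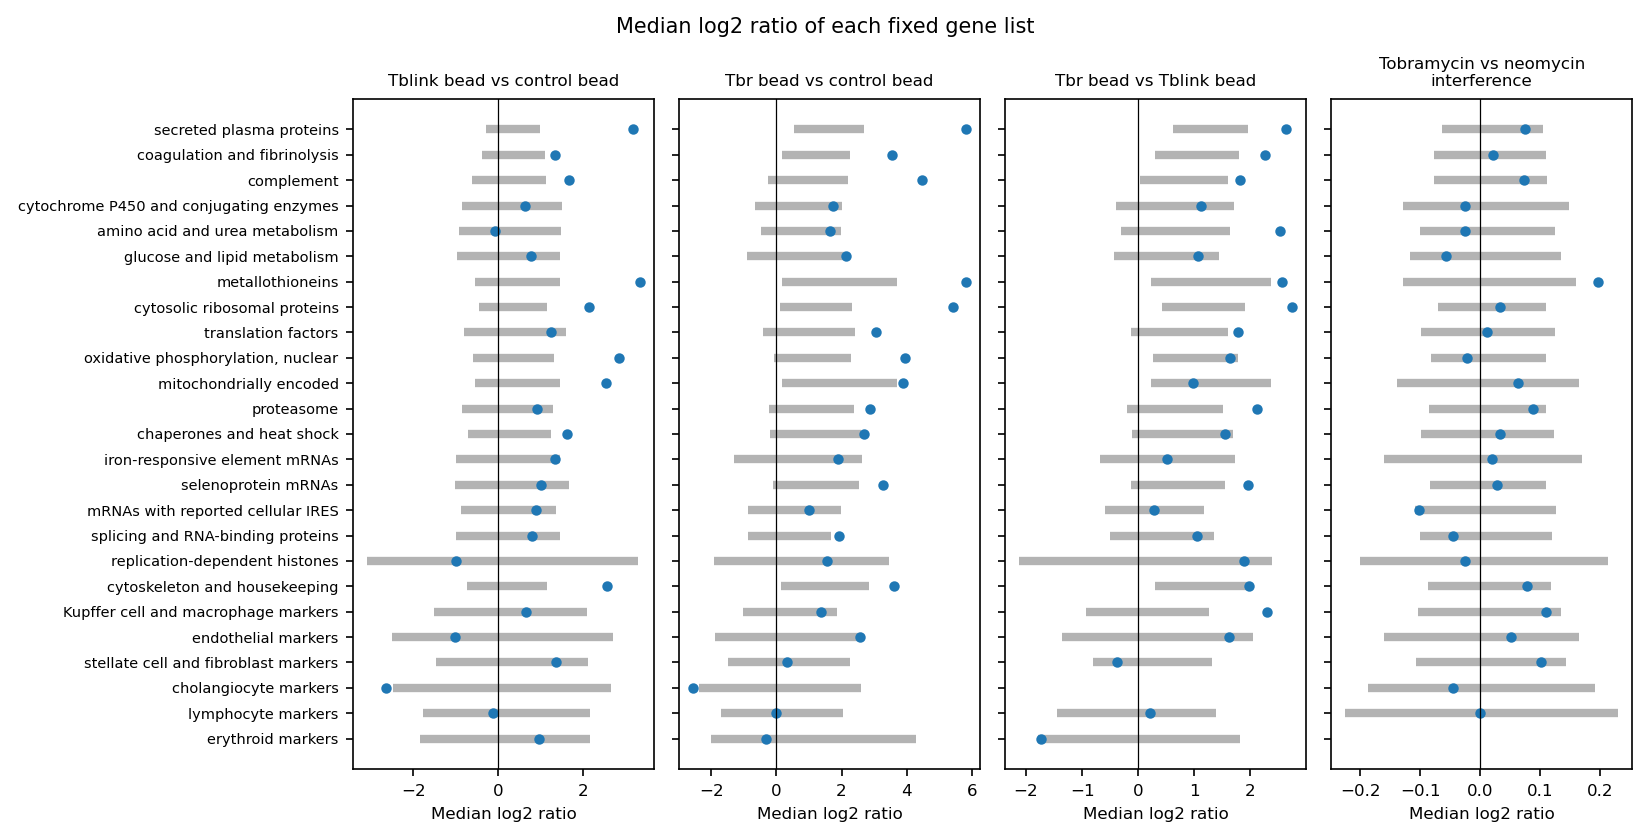
Median log2 ratio of each gene list (points) in 4 comparisons at the common trimmed mean. Grey bars give the central 95% of 10000 random lists matched on the decile of signal, which does not match the brightest members. The x axes differ between panels. Plasma protein, metallothionein and ribosomal protein lists lie above the bars in the bead comparisons, though at equal hybridization controls, with the dimmer bead near the floor, no list measured there does, while medians of tobramycin against neomycin lie between -0.10 and 0.20.

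Tobramycin and neomycin are aminoglycosides with a deoxystreptamine ring that differ in the ring positions carrying sugars and in the number of sugars. Their interference arrays were compared to ask whether they affect the hybridization of different mRNAs. Neither dose is given, so the doses may not match. Without an array of liver mRNA free of aminoglycoside, closeness may mean equal effects or no effect of either. F9 had 23709 with tobramycin and 24901 with neomycin, CYP2E1 27109 and 22877, the mitochondrial chaperone gene HSPD1 22884 and 24583 and KRT18 25012 and 21599.7. HP (46174 and 45883) and SERPINA3 (55299 and 53001) lay near the highest signals of these arrays, 57412 and 53001, where closeness says little. Of 16399 bright probe sets 99.5% differed by less than 2-fold, and the central 95% of log2 ratios ran from -0.58 to 0.57. For the 3104 with at least 3000 it ran from -0.47 to 0.36, and for the 2753 of them under 20000 on both, a limit chosen after the data were seen, from -0.49 to 0.37. The probe set spread was 0.24 on the log2 scale, and Spearman's rho across all probe sets was 0.95.

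At 4-fold 4 probe sets were higher with tobramycin and 1 was lower. Chosen after their values were seen, the higher ones were NAV1 (536 with tobramycin), RASSF4 (564), BAZ2A (462) and an unnamed probe set (455). The lower one was LILRA3 (428 with neomycin). The dimmer value of each was under the median of its array, 121 on both. NAV1, RASSF4 and BAZ2A did not meet the rule for named genes. Either another probe set represented the gene or another bright one had the opposite sign. Under the rule for named genes ARHGAP27 (2.75-fold), PALM (2.56-fold) and CAPN10 (2.48-fold) were higher with tobramycin, and TRMT10A (3.004-fold), OMD (2.92-fold) and KMT5A (2.79-fold) lower. ACADS, a short-chain acyl-CoA dehydrogenase, had 1263 with tobramycin and 598 with neomycin, and QNG1 738 and 2022.

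In the measured lists 0 members differed by 4-fold. Metallothioneins were the only list beyond its range (0 of 7 higher and 0 lower, median 0.20, range -0.13 to 0.16). Their members can share target. At equal controls the median was 0.16 and the range -0.17 to 0.12. Between these arrays that scaling shifts a list's median and its range nearly alike, so it is no separate check. With this many lists compared, 1 beyond its range can occur by chance. MT1H was 1.28-fold, MT1E 1.27-fold, MT2A 1.16-fold and MT1X 1.15-fold higher with tobramycin. Iron-responsive element mRNAs (median 0.020), selenoprotein mRNAs (0.029), ribosomal proteins (0.034) and mRNAs with a reported internal ribosome entry site (-0.10) were within theirs. With 1 array each, the intervals describe these arrays and do not show that the molecules act alike.

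**Figure D3:**
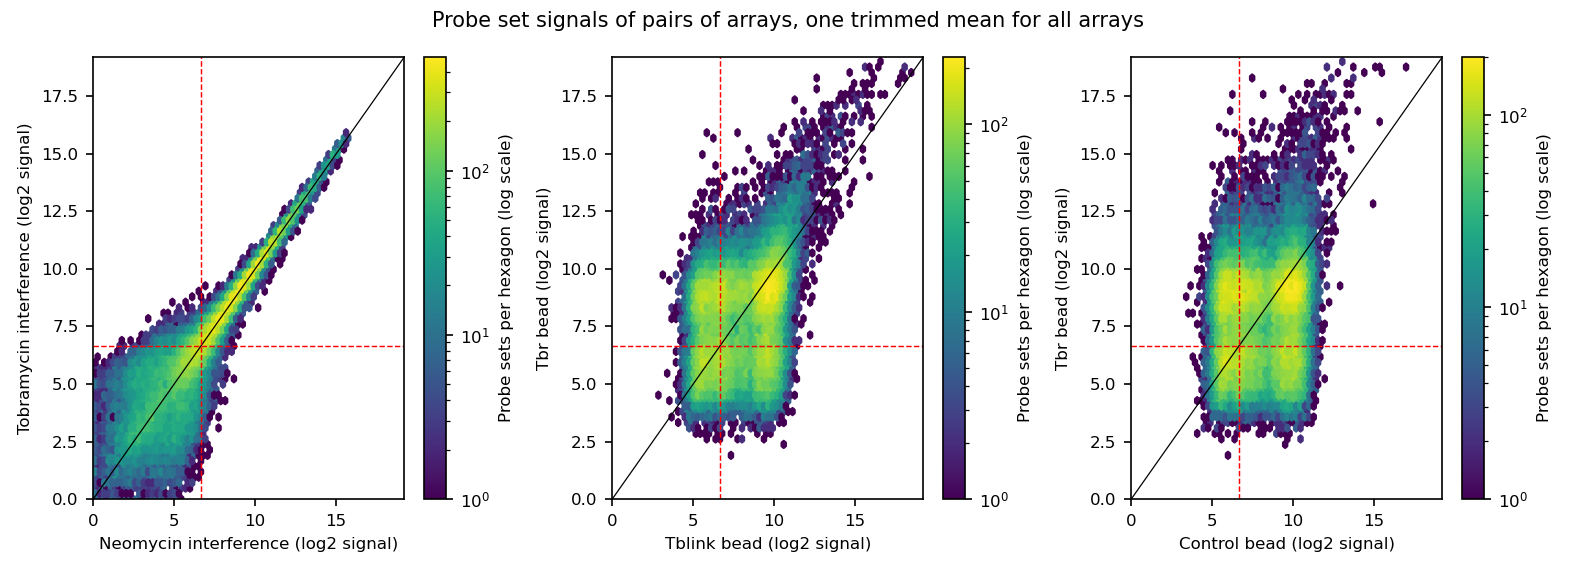
Log2 signals of 54613 probe sets on pairs of arrays at the common trimmed mean, coloured by probe sets per hexagon (log scale), with the floor of 100 dashed in red and equality as a diagonal. The interference arrays follow the diagonal, with a Spearman's rho of 0.95, against 0.29 for the Tblink and Tbr beads and 0.12 for the control and Tbr beads.

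Each interference array was last set beside the control bead, the only sample named a control; format and ligand cannot be told apart. FGG was at least 149-fold higher with tobramycin and at least 147-fold with neomycin, RPS18 at least 138-fold and at least 132-fold, and TTR, transthyretin, at least 116-fold and at least 119-fold. IFITM2, an interferon-induced membrane protein, was at least 130.3-fold and at least 117-fold higher, and LDHA at least 133-fold and at least 129-fold. HP was 1.10-fold and 1.09-fold higher, and 134-fold and 137-fold at equal controls. As it lay near the highest signals of both interference arrays, these folds may be too low. RPS6 was 1.32-fold and 1.28-fold lower, but 92.8-fold and 97.9-fold higher at equal controls.

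Secreted plasma proteins stood above their range with tobramycin (16 of 18 higher and 0 lower, median 4.23, range 1.18 to 3.04) and neomycin (16 of 18 higher and 0 lower, median 4.26, range 1.18 to 2.99). So did ribosomal proteins (medians 4.60 and 4.55), complement (4.58 and 4.49), housekeeping genes (4.51 and 4.44) and selenoprotein mRNAs (4.04 and 3.99). Markers of Kupffer cells (3.10 and 2.95), stellate cells (3.58 and 3.48) and endothelium (2.82 and 2.70) were above theirs too. CD14, a monocyte and macrophage receptor, was at least 57.5-fold and at least 53.5-fold higher, and LUM, a matrix proteoglycan, at least 43.5-fold and at least 53.3-fold. Cholangiocyte markers (2.21 and 2.32), mitochondrially encoded genes (1.94 and 1.98), lymphocyte markers (-0.11 and -0.23) and erythroid markers (-2.91 and -2.91) lay within theirs. Of the mitochondrially encoded genes ND4, at 53557 with tobramycin, lay near the top of that array. With tobramycin metallothioneins were within their range (6 of 7 higher and 0 lower, median 3.47, range 0.62 to 3.79). Iron-responsive element mRNAs were just above theirs there (5 of 8 higher and 2 lower, median 3.12, range -1.31 to 3.05). RAD51D, a recombination gene, was 118-fold and 109-fold lower by its brightest probe set, but 1.04-fold and 1.16-fold higher at equal controls.

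The counts were 8161 probe sets at least 4-fold higher and 14216 lower with tobramycin (36.5% higher) and 8210 and 14218 with neomycin (36.6% higher), at probe set spreads of 2.07 and 2.07 on the log2 scale. With the minimum of 3000 they were 2481 and 72, and 2476 and 66. This largely follows from the minimum, reached by 2919 and 2926 probe sets against 178 on the control bead array. At equal controls 15366 and 15552 were higher and 0 lower, which that scaling fixes because it puts nearly all control bead values at the floor. A list's median there only follows its signal on the interference array, on which the random lists are matched, so list ranges at equal controls decide nothing in these comparisons.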

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

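The test of GAPDH 3′ representation was chosen after its result was seen. The human control probe sets on the arrays were used in no comparison, and some had at least 4-fold the control bead signal at the common trimmed mean. The 3′ probe set of GAPDH, a glycolytic enzyme, had 4.25-fold on the Tblink bead, 39.1-fold on the Tbr bead, 11.9-fold with tobramycin and 12.01-fold with neomycin. The 3′ probe set of ACTB, cytoplasmic actin, had 6.04-fold on the Tbr bead, 15.7-fold with tobramycin and 14.5-fold with neomycin. The 3′ probe set of 18S ribosomal RNA had 7.28-fold, 9.97-fold and 10.01-fold on the same arrays. At equal controls the control bead signals of these 3 probe sets, 20.7, 18.5 and 8.64, were under the floor, as was GAPDH on the Tblink bead (74.0), so the folds are against background. The probe set for Alu repeats had 4.06-fold on the Tblink bead, and at equal hybridization controls 2704 on the control bead, 9193 on the Tblink bead, 16395 on the Tbr bead, 45648 with tobramycin and 45902 with neomycin.

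The 3′ signal of GAPDH was 188 times its 5′ signal on the Tbr bead array, 10.9 times on the control bead, 7.58 times on the Tblink bead, and 1.18 times with tobramycin and 1.18 times with neomycin. For ACTB the ratios were 20.3, 2.85, 10.2, 1.47 and 1.54 in that order. On the control and Tblink beads the 3′ signals at equal controls were themselves under the floor, for GAPDH 20.7 and 74.0 and for ACTB 18.5 and 25.1. Their ratios may thus compare background with background. On the Tbr bead the 3′ signals were above the floor, at 3843 for GAPDH and 529 for ACTB. By the ratios of 188 and 20.3 both 5′ signals on the Tbr bead were under the floor at equal controls. They thus count as background, and these ratios are not exact. Broken RNA or shortened labelled target may each give 5′ signals that low. These cannot be told apart from a pair of control genes, and no biological explanation was tested.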

How the results depend on the processing

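No paired analysis was possible because each group holds 1 array, and for the same reason none was left out in turn. The brightness minimum of 3000 was chosen after the data were seen, as were the values as deposited and the control scaling for lists and genes. Signal over background limits the bead arrays: at equal hybridization controls 9 probe sets of the control bead array, 95 of the Tblink bead array and 2226 of the Tbr bead array were above the floor, against 29599 of the neomycin array.

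Probe sets at least 4-fold higher and lower moved with most settings. With a brightness minimum of 1000 they were 4673 and 4787 for Tblink against control bead, 4421 and 5049 for Tbr against control bead, 2833 and 3169 for Tbr against Tblink bead, 0 and 0 for tobramycin against neomycin, 5359 and 6931 for tobramycin against control bead, 5378 and 6941 for neomycin against control bead. In the same order they were 320 and 28, 1561 and 34, 930 and 20, 0 and 0, 2481 and 72, 2476 and 66 with a minimum of 3000; fewer probe sets enter by construction, and in comparisons with a bead array most enter through the array that has more bright ones, which largely sets the split. They were 6569 and 6482, 5701 and 6750, 3843 and 4782, 0 and 0, 6128 and 9271, 6124 and 9285 with a floor of 200, and 6569 and 6482, 5705 and 6752, 3846 and 4783, 0 and 0, 6128 and 9274, 6126 and 9289 with the values as deposited, where the same floor and minimum act on values with a lower trimmed mean. At equal hybridization controls they were 16 and 0, 531 and 0, 527 and 0, 4 and 1, 15366 and 0, 15552 and 0, where nearly all control bead values are at the floor and few probe sets of any bead array reach the minimum. Quantile normalization gave 25 and 23 for tobramycin against neomycin and left the other counts within 1.5 times; the cause was not tested. Without _x_at and _s_at probe sets, so with fewer tested, 6060 were higher for Tbr against control bead, 4994 for Tbr against Tblink bead, 4212 for tobramycin and 4307 for neomycin against control bead, and 0 were lower for tobramycin against neomycin. A floor of 50 cannot move the counts, since 400 is 4 times 100.

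In the 6 planned comparisons the sign of a list median was opposite to the main one for 8 of 95 at equal controls, 13 of 148 with quantile normalization, 5 of 148 with the mean of a gene's probe sets, 0 of 148 with a floor of 200, 0 of 148 with one of 50 and 8 of 145 with the values as deposited. In the 2 added ones it was opposite for 8 of 48 at equal controls, the only other scaling whose list medians were kept there. A common floor cannot turn the sign of a gene's log2 ratio, so the outcome with floors of 50 and 200 was nearly fixed beforehand. Counting each named gene once per comparison, 317 cases moved by more than the probe set spread at equal controls, 394 moved less, and 5 past 4-fold turned. In that order the cases were 103, 606 and 7 with quantile normalization, and 58, 645 and 4 with the mean of probe sets. Outside tobramycin against neomycin the spreads were 2.07 to 2.44, so a 4-fold change can vanish and still count as moved less. A gene at the floor on both arrays cannot turn. These counts therefore do not show that the named genes are stable.

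Named genes past 4-fold that turned direction did so as follows, in log2 ratios; the cause was not tested. With quantile normalization COX2 had -0.045 for Tblink and -0.19 for Tbr against control bead, APOC1 -0.76 and -0.73 for tobramycin and neomycin against control bead, MT1H -0.67 and -1.07, and RPL27 -0.39 for tobramycin. As the mean of probe sets C1S had -0.030 and SRSF3 -0.36 for Tbr against control bead, and EPAS1 -0.17 and -0.062 for tobramycin and neomycin. At equal controls RAD51D had 0.055 and 0.21, CGAS 0.16 and LOC105374690 0.43 for tobramycin, and SIGLEC6 0.38 for neomycin.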

Other observations

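The Tbr bead array was also set beside the tobramycin array, a comparison across formats chosen after the data were seen. At the common trimmed mean signals on the tobramycin array ran to 57412, with ORM1 (53868), ND4 (53557) and COX1 (50563) near that top. On the Tbr bead array APOC1 had 520665. The upper limit of the tobramycin array may thus add to the folds of its brightest genes, which was not tested. At the common trimmed mean metallothioneins were above their random-list range (6 of 7 higher and 0 lower, median 2.62, range -1.63 to 1.65), as were secreted plasma proteins (10 of 18 higher and 2 lower, median 2.18, range -1.01 to 0.99), mitochondrially encoded genes (3 of 7 higher and 0 lower, median 1.73, range -1.66 to 1.52) and ribosomal proteins (3 of 17 higher and 5 lower, median 1.05, range -1.10 to 1.02). Cholangiocyte (0 of 7 higher and 7 lower, median -4.14, range -1.30 to 1.91), stellate cell (0 of 11 higher and 7 lower, median -2.40, range -1.36 to 1.07) and Kupffer cell markers (2 of 14 higher and 5 lower, median -1.58, range -1.17 to 0.75) were below theirs, as were mRNAs with a reported internal ribosome entry site (1 of 13 higher and 5 lower, median -1.47, range -1.24 to 1.03) and complement genes (0 of 17 higher and 2 lower, median -1.26, range -1.12 to 0.97). At equal hybridization controls the median of all bright genes moved from 0.44 to -3.45, and all measured lists had medians below 0, from -6.53 to -2.07, so the lists above 0 turned direction and those below kept theirs. On the Tblink bead against the tobramycin array mitochondrially encoded genes were above their range (2 of 7 higher and 0 lower, median 0.75, range -2.87 to -0.13) and ribosomal proteins below (0 of 17 higher and 11 lower, median -3.18, range -2.41 to -0.70). At equal controls, with nearly all Tblink bead values at the floor, both lists were lower on the Tblink bead (medians -6.08 and -8.13), so the direction of the mitochondrially encoded genes turned.

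In the main setting 8378 probe sets were at least 4-fold higher on the Tbr bead than with tobramycin and 4044 lower (67.4% higher). The split was 2759 and 2778 with a floor of 200, and 2761 and 2778 with the values as deposited. It was 5195 and 5762 with quantile normalization and 1700 and 2406 with a minimum of 1000. Without _x_at and _s_at probe sets it stayed, at 6372 and 2057. With at least 3000 on either array, 450 of 3679 probe sets were higher and 1137 lower (28.4% higher). At equal controls, over 15367 probe sets with at least 400, 1 was higher and 15175 lower. Among the 450 higher ones, 45.6% were also at least 2-fold higher on the Tblink bead than with neomycin, against 6.44% of all as bright, a ratio of 7.07 (95% resampling interval 6.45 to 7.71). A property of capture that both beads share may account for part of this. The tobramycin and neomycin arrays are so alike (Spearman's rho 0.95) that a probe set dim on one is dim on the other, which raises the ratio by itself, and its size was not tested. No biological explanation was tested.

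Probe sets lower on a bead than on the control bead may reflect background of the control bead array raised by scaling. If so, another probe set of the same gene should be lower about as often as any bright probe set. For the Tblink bead the ratio of these shares was 1.004 (0.96 to 1.05), below the bound of 1.2 set beforehand. For the Tbr bead it was 1.15 (1.10 to 1.201), an interval that reaches the bound, so the test does not decide. Higher probe sets gave 1.05 for the Tblink bead, 1.15 for the Tbr bead, 1.35 for tobramycin and 1.36 for neomycin, each against the control bead, and lower ones 1.44 for tobramycin and 1.46 for neomycin. The higher ones of both beads were thus below 1.2 as well. Lower ones with tobramycin and neomycin were above it, though made against the same control bead array. So the ratio cannot tell control bead background from RNA, and it decides for neither bead.

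RAD51D, singled out after its values were seen, had at equal hybridization controls 238 on the control bead, 165 on the Tblink bead, 269 on the Tbr bead, 247 with tobramycin and 275 with neomycin. These values are from its brightest probe set, and another is not given here. TF ran from 99.7 to 35538 over the same arrays. Whether the nearly level RAD51D signal comes from RAD51D mRNA was not tested.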
